A study of Mus musculus with 12 samples.

How the data were processed

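The data are 12 RNA sequencing libraries of mouse left ventricle, 3 from each combination of surgery (MI or sham) and genotype (Cre positive or Cre negative). Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.5 to mm10 and quantified with RSEM 1.2.12. Per the file headers, the deposited file of each library gives RSEM expected counts per gene and FPKM values (fragments scaled to transcript length and library size), which the authors computed. A deposited table joins the FPKM of all 12 libraries, and its values equal those of the library files (largest difference 0.0), with 0 where a library file does not list a gene. The authors also deposited 4 comparison tables made with DESeq2, per the labels of those files, holding a signal value per group scaled within the comparison, log2 fold changes and p-values with adjusted p-values. The group signal values in these deposited tables have no stated unit and were not used, and counts of genes with an adjusted p under 0.05 in the authors' tables are quoted beside the counts computed here.

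The library files list 17471 genes by Entrez identifier and symbol, all with RefSeq NM transcripts, and 17436 of them were matched by identifier to the RefSeq annotation table of the mouse genome for positions. Genes that a library file leaves out were set to 0. Expected counts were rounded to whole numbers before testing, and 74.0% of the values above 0 were whole to the 2 decimals given. Total expected counts per library were 10257675 to 15176286, the largest 1.48 times the smallest, and 14988 to 16016 genes had counts above 0 per library. Counting intervals and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group held 0 reads of a gene over its 3 libraries, the fold was computed against 3 reads over the group, and with 1 to 3 reads a ratio is given with its 95% counting interval.

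Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10), which left 13678 and removed 3793. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries (residual degrees of freedom 8, prior degrees of freedom 4.16, common dispersion 0.0272). Contrasts were injury in each genotype (MI minus sham), genotype after each surgery (Cre positive minus Cre negative) and the difference of the injury response between genotypes. P-values are two-sided and were adjusted by Benjamini and Hochberg's method within each contrast, with calls at an adjusted p under 0.05. Errors of log2 fold changes are the standard errors of this model, and errors of CPM are standard deviations over 3 libraries. For 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so no such test is reported.

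The tests, alternatives, gene lists and the rule for naming genes were fixed in advance. That rule takes, in each pairwise contrast, the 12 genes with the largest rise and the 12 with the largest fall among those called, with a mean log2 CPM of at least 1, no overlap between the libraries compared and no predicted-gene name. Where no gene is called, the 5 smallest p-values are given. It adds Yap1 and Postn in every contrast, up to 4 members with the smallest p from each list described and up to 2 called members that go against their list. A few genes that meet this rule are not reported here. The genes quoted for Cre-positive sham replicate 2 were chosen after their values were seen.

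Of 44 gene lists 42 had at least 3 measured members and were tested. The list of X inactivation transcripts had 0 measured members and that of genes encoded in mitochondria was too short as well, so neither was tested. Lists were compared with all other genes by camera in limma 3.58.1 on log2 CPM with the preset correlation of 0.01 between genes, adjusted over the 42 lists in each contrast, and again with a correlation estimated from the data and with fry. Counts of members are given over all genes and adjusted over the list alone. Some lists share members. Spp1 stands in the cytokine and osteogenic lists, Tnc and Postn in the matrix and myofibroblast lists, and Yap1 in the Hippo list. Lists of cell type markers describe whole tissue and name no cell by themselves.

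On simulated data with 50 genes raised or lowered at each fold, 30% of genes changed 1.5-fold and 96% of genes changed 4-fold were recovered in the Cre-negative injury contrast, and 12% and 96% in the contrast of genotypes after MI. Unchanged genes made up 3.36 to 7.1% of the calls in the 4 pairwise contrasts, and 0 of 42 lists were called where nothing was changed. Genes were simulated independently of each other, so this check of the lists does not cover genes that move together. No pair of libraries within a group held identical counts.

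Each result was refitted with size factors by the median of ratios (RLE), no filter on low counts, a filter of 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a fit to only the 2 groups compared, glmTreat against a fold of 1.5 and with each library left out in turn. These settings were also chosen before the data were examined. The limma-trend fits on FPKM did not apply the TMM factors. Chosen after seeing the data were a term for the presence of Y-linked reads (at least 10 CPM), a comparison of libraries of the same Y-linked status, and the Y-linked term with Cre-positive sham replicate 2 left out. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. Transcript isoforms and the reads over the floxed exon were not analysed here.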

Results

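Left ventricles of mice with a floxed Yap gene were profiled by RNA sequencing 4 days after permanent ligation of the left anterior descending coronary artery, a model of myocardial infarction (MI), or after sham surgery. Cre-positive mice carried 1 copy of the inducible recombinase MerCreMer at the endogenous Postn locus, which is switched on in activated fibroblasts, and Cre-negative siblings had a wildtype Postn locus. All animals received tamoxifen in the diet from the day of surgery and were 6 to 10 weeks old. The 12 libraries formed 4 groups with n = 3 each, and the labels say no more about the replicates than a number within each group. P-values of single genes therefore rest on the spread between these samples, estimated over all 4 groups. P-values of lists with the preset correlation instead compare the members with other genes and take them as nearly independent. Total expected counts, the gene-level read estimates, ranged from 13823268 to 15176286 in Cre-negative MI, 13609502 to 14132503 in Cre-positive MI, 10257675 to 11726159 in Cre-negative sham and 10679705 to 13608483 in Cre-positive sham libraries. Of 17471 genes, 13678 had enough counts to be tested, and 3 counts, the floor used for absent genes, correspond to 0.198 to 0.292 CPM (counts scaled to library size) in a library.

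Surgery separated the libraries along the first principal component, which held 74.0% of the variance. On that axis the Cre-negative MI libraries lay at 68.0 to 79.2, the Cre-positive MI libraries at 43.6 to 55.1, the Cre-negative sham libraries at -61.0 to -49.2 and the Cre-positive sham libraries at -80.8 to -59.8. Cre-positive sham replicate 2 stood apart on the next component, with 7.6% of the variance, at 57.8 against -21.4 to 14.7 in the other 11 libraries. In that library the slow myosin gene Myh7 reached 34060 CPM, against 377 to 2938 CPM in the other sham libraries, and the fast myosin gene Myh6 had 14340 CPM against 39840 to 53140. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were read in 3 of 3 Cre-negative MI, 2 of 3 Cre-negative sham, 1 of 3 Cre-positive MI and 0 of 3 Cre-positive sham libraries, taking 10 CPM over the 4 genes as present. The sexes were thus spread unevenly over the genotypes.

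**Figure D1:**
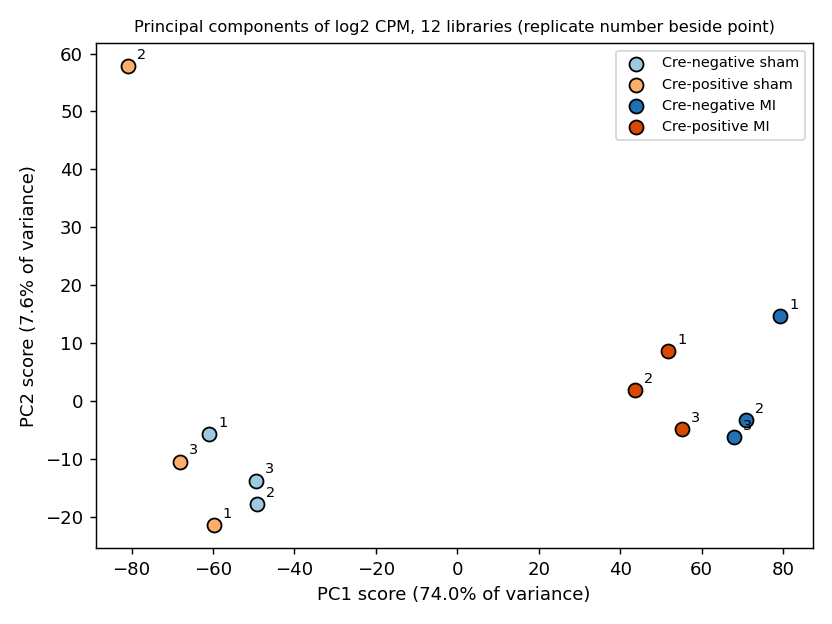
Scores of the 12 libraries on the first (horizontal, 74.0% of the variance) and next (vertical, 7.6%) principal components of log2 CPM, coloured by group. MI and sham libraries separate along the horizontal axis, and Cre-positive sham replicate 2 lies alone at 57.8 on the vertical axis.

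The floxed gene itself, Yap1 (Entrez 22601, mm10 chromosome 9, 7931999 to 8004638), encodes the transcriptional coactivator at the end of the Hippo pathway. It was read in all 12 libraries, at similar levels in both genotypes after each surgery, and every sham library lay above every MI library. Yap1 stood at 93.9, 92.9 and 91.1 CPM in Cre-positive MI, 84.6, 96.4 and 94.0 in Cre-negative MI, 121, 102 and 107 in Cre-positive sham and 116, 115 and 114 in Cre-negative sham libraries 1 to 3. Its log2 difference between Cre-positive and Cre-negative hearts was 0.02 ± 0.09 after MI (SE, n = 3 per group, adjusted p = 0.971) and -0.06 ± 0.09 after sham surgery (adjusted p = 0.843). Gene-level counts of whole ventricle do not resolve the floxed exon, and the design directs recombination only to cells that express Postn. Postn (Entrez 50706, mm10 chromosome 3, 54359267 to 54391041), the matrix protein gene whose locus carries the recombinase, had 1590, 1528 and 1729 CPM in Cre-negative MI and 603, 628 and 674 CPM in Cre-positive MI libraries. In sham libraries Postn had 111, 86.8 and 62.7 CPM without the recombinase and 10.2, 3.76 and 11.5 CPM with it.

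The first comparison asked what infarction changes in hearts without the recombinase. Many genes of matrix, inflammation and cell division rose, and many of muscle contraction and energy metabolism fell. Spp1, which encodes the secreted phosphoprotein osteopontin, rose by 7.88 ± 0.27 on the log2 scale (SE, n = 3 per group, adjusted p = 7.38e-09), or 236-fold. The metalloprotease gene Adam8 rose by 6.19 ± 0.27 and the macrophage lectin gene Chil3 by 6.56 ± 0.50. The cyclin-dependent kinase gene Cdk1 rose by 5.82 ± 0.31, and Postn rose by 4.22 ± 0.31 (adjusted p = 6.49e-07). Yap1 fell by 0.33 ± 0.09 on the log2 scale (adjusted p = 0.00751).

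Among the other largest rises in Cre-negative hearts were the haptoglobin gene Hp (6.81 ± 0.96), the fibrillar collagen gene Col11a1 (6.03 ± 0.30), the chemokine gene Cxcl13 (6.02 ± 1.39), the arginase gene Arg1 (5.97 ± 0.52) and Gpnmb (5.92 ± 0.40), all as log2 fold changes ± SE. Col6a5, Depdc1a and Kntc1 also rose, from 1, 2 and 2 reads over the 3 sham libraries, with ratios of 140 (95% counting interval 24.9 to 5570), 78.5 (21.5 to 652) and 75.3 (20.6 to 625). The largest falls were those of Inmt (-2.85 ± 0.89), the potassium channel gene Kcnv2 (-2.74 ± 0.37), Cngb3 (-2.55 ± 0.30), the carboxylesterase gene Ces1d (-2.52 ± 0.28) and Tnfrsf19 (-2.39 ± 0.36). The chloride channel gene Clcn1 fell as well. Cyp26b1, Stum, the sodium channel subunit gene Scn4b, Sbk3 and Klhl33 fell by 2.31, 2.30, 2.12, 2.06 and 2.02 on the log2 scale. Inmt lost its call without Cre-negative MI replicate 2 (adjusted p = 0.0601) or 3 (0.0595) or Cre-negative sham replicate 1 (0.0663), and Sbk3 lost it without Cre-negative MI replicate 2 (0.0567).

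Matrix genes rose together in Cre-negative hearts. All 19 measured collagens rose, with a median log2 fold change of 3.06 (adjusted p = 2.1e-09, adjusted p = 0.243 with an estimated correlation), among them Col12a1 (5.03 ± 0.19) and Col5a2 (3.62 ± 0.21). Of 36 matrix glycoproteins and crosslinking enzymes 32 rose and 1 fell, with a median of 2.43 (adjusted p = 4.83e-12, 0.147 with an estimated correlation), among them the tenascin gene Tnc (5.24 ± 0.25) and Sparc (2.44 ± 0.15), while the latent TGF-beta binding protein gene Ltbp1 fell by 0.55 ± 0.18 on the log2 scale. All 16 myofibroblast markers rose (median 3.54, adjusted p = 2.03e-09, 0.161 with an estimated correlation), among them Wisp1 (3.76 ± 0.12), the smooth muscle protein gene Tagln (3.33 ± 0.14) and Cthrc1 (4.87 ± 0.27). Of 26 matrix proteases and their inhibitors 20 rose and 1, Timp4 (-1.10 ± 0.42), fell (median 2.56, adjusted p = 6.97e-08, 0.0928 with an estimated correlation). Of 22 TGF-beta signalling genes 14 rose and 3 fell (median 0.89, adjusted p = 0.00165, 0.147 with an estimated correlation), with Tgfbi at 2.38 ± 0.13 and the receptor gene Tgfbr3 at -0.61 ± 0.19. Of 21 cytoskeletal targets of MRTF and SRF 16 rose and 1, Tpm1 (-0.69 ± 0.14), fell (median 1.96, adjusted p = 1.72e-06, 0.243 with an estimated correlation). Of 16 resting fibroblast markers 6 rose and 2, Scara5 (-1.45 ± 0.20) and Gsn (-1.29 ± 0.18), fell, and the list was not called (adjusted p = 0.739).

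Immune and proliferation genes rose in the same hearts. Of 24 macrophage and monocyte markers 23 rose and 0 fell (median 3.10, adjusted p = 7.25e-10, 0.243 with an estimated correlation), among them Lgals3 (5.76 ± 0.30), Trem2 (4.25 ± 0.22) and Cd68 (4.06 ± 0.22). Of 12 neutrophil markers 10 rose, including the growth factor receptor gene Csf3r (3.06 ± 0.25) and Mmp9 (3.88 ± 0.46), and 1, G0s2 (-0.77 ± 0.26), fell (median 3.31, adjusted p = 0.003, 0.299 with an estimated correlation). Of 37 cell cycle genes 35 rose and 0 fell (median 3.76, adjusted p = 6.17e-17, 0.0928 with an estimated correlation), with the kinesin gene Cenpe at 4.94 ± 0.23 and the cyclin gene Ccnb2 at 5.08 ± 0.25. Of 30 cytokines and chemokines 23 rose and 0 fell (median 2.90, adjusted p = 6.26e-07, 0.243 with an estimated correlation), such as Ccl9 (2.88 ± 0.22). Of 32 interferon-stimulated genes 20 rose and 0 fell (median 1.08, adjusted p = 0.000154, 0.601 with an estimated correlation), among them Ddx58 (1.16 ± 0.12), Oas1a (2.47 ± 0.31) and Mx1 (3.39 ± 0.43).

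Muscle and metabolic genes fell in Cre-negative hearts. Of 23 cardiomyocyte genes 20 fell and 0 rose (median -1.04, adjusted p = 8.92e-08, 0.256 with an estimated correlation), among them the calcium pump regulator gene Pln (-1.32 ± 0.15) and the troponin gene Tnni3 (-1.37 ± 0.16). All 51 oxidative phosphorylation genes fell (median -0.92, adjusted p = 1.11e-20, 0.243 with an estimated correlation), with the complex I subunit gene Ndufb9 at -1.06 ± 0.09. All 20 genes of the tricarboxylic acid cycle fell (median -0.97, adjusted p = 1.3e-10, 0.243 with an estimated correlation), such as Idh3b (-1.10 ± 0.11). Of 30 fatty acid oxidation genes 24 fell and 0 rose (median -1.10, adjusted p = 2.1e-09, 0.299 with an estimated correlation), with Etfb at -1.22 ± 0.10. Of 25 ion channel and conduction genes 20 fell and 3 rose (median -0.85, adjusted p = 6.87e-05, 0.243 with an estimated correlation), with Kcnj11 at -1.26 ± 0.12 against the connexin gene Gja5 at 1.29 ± 0.23.

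Genes of the pathway that the design targets moved both ways after infarction. Of 23 targets of YAP and TEAD in Cre-negative hearts 12 rose and 6 fell (median 0.65), and the list was not called (adjusted p = 0.175). Myof (2.91 ± 0.18), the survivin gene Birc5 (4.27 ± 0.31) and Ccdc80 (1.52 ± 0.13) rose, while the tissue factor gene F3 fell by 1.18 ± 0.14 and Crim1 by 0.47 ± 0.08 on the log2 scale. Of 23 Hippo pathway components 8 rose and 4 fell (median 0.15, adjusted p = 0.557), with the kinase gene Stk4 at 0.66 ± 0.08 and the cofactor gene Vgll3 at 1.99 ± 0.26 against the transcription factor gene Tead1 at -0.48 ± 0.11.

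Smaller groups of genes were called in Cre-negative hearts as well. Of 19 complement genes 13 rose and 0 fell (median 1.15, adjusted p = 0.000672, 0.283 with an estimated correlation), such as Cfb (2.46 ± 0.22). Of 14 chondrogenic and osteogenic genes 8 rose and 1, Wif1 (-1.28 ± 0.36), fell (median 1.70, adjusted p = 0.0126, 0.161 with an estimated correlation). Of 21 genes of the cardiac stress programme 13 rose, such as the natriuretic peptide gene Nppa (2.55 ± 0.36), and 1, Tnnt1 (-1.21 ± 0.26), fell (median 0.77, adjusted p = 0.0136, 0.444 with an estimated correlation). Of 22 unfolded protein response genes 12 rose, such as Edem1 (2.19 ± 0.14), and 2 fell, among them Herpud1 (-1.40 ± 0.17) (median 0.58, adjusted p = 0.0118, 0.595 with an estimated correlation). Of 39 ribosomal protein genes 32 rose and 0 fell (median 0.39, adjusted p = 1.95e-06, 0.509 with an estimated correlation), with Rpl3 at 1.04 ± 0.11. Of 16 circadian genes 7 fell, such as Hlf (-1.75 ± 0.17), and 1, Arntl (1.16 ± 0.46), rose (median -0.74, adjusted p = 0.0118, 0.201 with an estimated correlation). Of 10 adipocyte markers 6 rose and 0 fell (median 3.85, adjusted p = 0.0499, 0.649 with an estimated correlation), with Adipoq at 4.93 ± 1.10. The adipocyte call ended without Cre-negative MI 1 (0.112), Cre-negative MI 2 (0.0538), Cre-positive sham 1 (0.0738), Cre-positive sham 2 (0.0804), Cre-positive sham 3 (0.0608), Cre-negative sham 2 (0.0737) or Cre-negative sham 3 (0.0741). Of 24 immediate early genes 8 rose and 0 fell (median 0.74, adjusted p = 0.0283, 0.699 with an estimated correlation), such as Egr2 (3.72 ± 0.35), and the call ended without Cre-negative MI replicate 1 (0.0505) or Cre-negative sham replicate 1 (0.0755).

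Lists not called in Cre-negative hearts are given with the members that rose and fell, the median and the adjusted p. Markers of resident macrophages stood at 5 and 0 of 10 (0.48, 0.739), of T and NK cells at 4 and 0 of 6 (1.19, 0.228), of B cells at 4 and 0 of 7 (1.74, 0.096) and of dendritic cells at 4 and 0 of 13 (0.96, 0.228, called without Cre-positive sham replicate 2, 0.0144). Endothelial markers stood at 2 and 3 of 17 (0.05, 0.739), with Flt1 at -0.82 ± 0.14, and their mean of -0.04 had the other sign. Lymphatic markers stood at 2 and 2 of 7 (-0.28, 0.719), among them Pdpn (2.73 ± 0.14) and Prox1 (-1.42 ± 0.16). Markers of smooth muscle and pericytes stood at 5 and 4 of 14 (0.24, 0.739), with Cnn1 at 4.09 ± 0.38 and Abcc9 at -1.60 ± 0.15. Epicardial markers stood at 8 and 2 of 13 (1.10, 0.096), nerve markers at 4 and 0 of 10 (0.12, 0.739) and erythrocyte markers at 0 and 0 of 8 (0.65, 0.719). Atrial markers stood at 2 and 1 of 6 (-0.75, 0.759), with a mean of 0.09. Glycolysis stood at 6 and 11 of 24 (-0.17, 0.325), with a mean of 0.08, between Slc16a3 (3.34 ± 0.20) and Ldhb (-1.36 ± 0.12). Hypoxia genes stood at 7 and 4 of 18 (0.13, 0.759), angiogenic growth factors at 9 and 5 of 23 (0.21, 0.551), with Igf1 at 2.43 ± 0.21 and Vegfb at -0.98 ± 0.14, and Y-linked genes at 0 and 0 of 4 (0.43, 0.719).

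By the edgeR quasi-likelihood test 7424 of 13678 genes changed in Cre-negative hearts, 4090 up and 3334 down, of which 2358 rose and 733 fell by at least 2-fold. The deposited comparison table of the authors held 7652 genes with an adjusted p under 0.05, 2336 of them higher and 796 lower by at least 2-fold. Adjusted over the list alone, the calls differed by no more than 3 genes in each list named for this comparison, except that 1 instead of 5 resident macrophage markers rose. Of 42 lists 24 were called with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0928, and 32 by fry, which tests whether a list moves on balance to one side.

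The next comparison asked the same of Cre-positive hearts. Spp1 rose by 9.61 ± 0.31 on the log2 scale (SE, n = 3 per group, adjusted p = 7.5e-09). Cthrc1, which encodes a secreted protein of activated fibroblasts, rose by 9.21 ± 0.40, the cornified envelope gene Sprr1a by 9.08 ± 0.43 and Postn by 6.23 ± 0.35 (adjusted p = 1.75e-07), each from a lower sham level than in Cre-negative hearts. Yap1 fell by 0.25 ± 0.09 on the log2 scale (adjusted p = 0.0364), a call that ended when any of 5 libraries was left out (Cre-positive MI replicates 1, 2 and 3, Cre-negative MI replicate 3 and Cre-positive sham replicate 1, adjusted p = 0.0753, 0.0796, 0.0967, 0.051 and 0.113).

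Several of the strongest rises in Cre-positive hearts started from almost no reads. Cthrc1 and Sprr1a held 6 and 13 reads over the 3 sham libraries. The acute phase gene Saa3 had 1 read over the 3 sham libraries and a ratio of 1180 (95% counting interval 211 to 46500), the scavenger receptor gene Marco had 1 read and a ratio of 606 (108 to 23900), and Arg1 had 2 reads and a ratio of 527 (146 to 4350). Against the floor of 3 reads over the group, the division genes Pbk, Cep55, Ncapg, Troap and Neil3 rose at least 64.6-fold, 56.3-fold, 48.1-fold, 35.8-fold and 35.3-fold, and Serpinb2 rose at least 50.6-fold. The largest falls were those of Inmt (-2.84 ± 0.83), Fam222a (-2.14 ± 0.51), the galectin gene Lgals4 (-2.11 ± 0.60), C1qtnf4 (-1.81 ± 0.26), Cyfip2 (-1.72 ± 0.23) and Clcn1 (-1.71 ± 0.42). Hsbp1l1, Pttg1, Carmil3, C2cd4b and Gnmt fell by 1.70, 1.68, 1.62, 1.62 and 1.61 on the log2 scale. Without Cre-positive sham replicate 2, the log2 fold changes of Inmt and Lgals4 shrank to -1.16 and -0.74 and were no longer called (adjusted p = 0.115 and 0.0544). Their calls also ended without Cre-positive MI replicate 3 (adjusted p = 0.0596 and 0.0535).

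The same gene groups moved in Cre-positive hearts. All 19 collagens rose (median 3.46, adjusted p = 3.04e-12, 0.208 with an estimated correlation), with Col12a1 at 5.77 ± 0.21, as did all 16 myofibroblast markers (median 3.47, adjusted p = 3.53e-12, 0.104 with an estimated correlation), with Wisp1 at 3.40 ± 0.12. Of 36 matrix glycoproteins and crosslinking enzymes 31 rose and 0 fell (median 2.53, adjusted p = 1.18e-15, 0.0712 with an estimated correlation), with Tnc at 8.01 ± 0.31. Of 26 proteases and inhibitors 21 rose and 0 fell (median 2.22, adjusted p = 2.93e-09, 0.0543 with an estimated correlation), and 23 of 24 macrophage markers rose and 0 fell (median 3.07, adjusted p = 1.63e-12, 0.208 with an estimated correlation), with Lgals3 at 5.77 ± 0.30. All 37 cell cycle genes rose (median 3.61, adjusted p = 1.63e-19, 0.0543 with an estimated correlation), with Cenpe at 5.18 ± 0.26. All 32 interferon-stimulated genes rose (median 1.67, adjusted p = 4.33e-09, 0.352 with an estimated correlation), with Oas1a at 2.93 ± 0.32. Of 12 neutrophil markers 7 rose and 0 fell (median 1.99, adjusted p = 0.0328, 0.395 with an estimated correlation), with Mmp9 at 2.23 ± 0.45. The list lost its call without Cre-positive sham replicate 2 (0.0767) or Cre-positive MI replicate 2 (0.0841) or 3 (0.0696).

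Muscle and metabolic genes fell in Cre-positive hearts too. Of 23 cardiomyocyte genes 15 fell and 0 rose (median -0.63, adjusted p = 2.28e-05, 0.352 with an estimated correlation), with Tnni3 at -0.88 ± 0.16. Of 51 oxidative phosphorylation genes 49 fell and 0 rose (median -0.63, adjusted p = 2.87e-17, 0.252 with an estimated correlation), with Ndufb9 at -0.71 ± 0.09. Of 20 tricarboxylic acid cycle genes 19 fell (median -0.67, adjusted p = 4.33e-09, 0.252 with an estimated correlation), and 26 of 30 fatty acid oxidation genes fell (median -0.87, adjusted p = 4.18e-09, 0.334 with an estimated correlation), with Etfb at -0.93 ± 0.10. Of 25 ion channel genes 10 fell and 3 rose (median -0.45, adjusted p = 0.00889, 0.352 with an estimated correlation), with Kcnj11 at -1.08 ± 0.12 and Gja5 at 1.12 ± 0.23. Of 23 YAP and TEAD targets 11 rose and 3 fell (median 0.30, adjusted p = 0.118), with Myof at 2.65 ± 0.18, Birc5 at 4.28 ± 0.32, F3 at -0.89 ± 0.14 and the phosphatase gene Ptpn14 at -0.61 ± 0.12. Without Cre-positive sham replicate 2 the YAP and TEAD list had a median of 0.63 and was called (0.0393).

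Lists outside these groups moved as follows in Cre-positive hearts. Of 22 TGF-beta signalling genes 12 rose and 1, Smad4 (-0.32 ± 0.09), fell (median 0.76, adjusted p = 0.00306, 0.122 with an estimated correlation). Of 21 MRTF and SRF targets 16 rose and 1, Srf (-0.57 ± 0.11), fell (median 1.52, adjusted p = 1.78e-06, 0.208 with an estimated correlation). Of 30 cytokines 22 rose and 0 fell (median 2.74, adjusted p = 1.79e-08, 0.208 with an estimated correlation). Of 19 complement genes 16 rose and 0 fell (median 1.45, adjusted p = 2.94e-05, 0.208 with an estimated correlation), with Cfb at 2.99 ± 0.22. Of 14 chondrogenic and osteogenic genes 9 rose and 0 fell (median 1.69, adjusted p = 0.00185, 0.0712 with an estimated correlation), with Sox9 at 2.75 ± 0.21. Of 13 epicardial markers 9 rose and 0 fell (median 1.16, adjusted p = 0.00889, 0.352 with an estimated correlation), and 9 of 10 adipocyte markers rose (median 4.84, adjusted p = 0.0105, 0.477 with an estimated correlation), with Adipoq at 5.17 ± 1.03.

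The calls of 6 further lists in Cre-positive hearts depended on single libraries or on the term for Y-linked reads. Markers of T and NK cells (4 of 6 rose, median 1.28, adjusted p = 0.0498, 0.208 with an estimated correlation), B cells (4 of 7, 1.81, 0.0391, 0.352 with an estimated correlation) and dendritic cells (4 of 13, 1.07, 0.0403, 0.465 with an estimated correlation, median 0.69 without Cre-positive sham replicate 2) lost their calls with that term at similar medians (1.33, 1.46 and 1.03, adjusted p = 0.0533, 0.0567 and 0.0533). The call for T and NK cells also ended without Cre-positive MI 3 (0.068). The call for B cells also ended without Cre-positive MI 1 (0.0676) or Cre-positive sham 2 (0.0797). Of 21 stress programme genes 9 rose, such as Nppa (1.94 ± 0.36), and 2, Tnnt1 (-0.71 ± 0.26) and Xirp1 (-0.69 ± 0.13), fell (median 0.53, adjusted p = 0.0498, 0.477 with an estimated correlation), and the median was 1.46 (0.00208) without Cre-positive sham replicate 2. That call ended without Cre-positive MI 2 (0.0505), Cre-positive MI 3 (0.0696), Cre-positive sham 1 (0.148) or Cre-positive sham 3 (0.108). Of 16 circadian genes 6 fell and 0 rose (median -0.47, adjusted p = 0.0391, 0.208 with an estimated correlation), with Hlf at -0.74 ± 0.16. That call ended without Cre-positive MI 3 (0.068), Cre-positive sham 1 (0.0589) or Cre-positive sham 3 (0.0637). Of 39 ribosomal protein genes 10 rose and 0 fell (median 0.17, adjusted p = 0.0328, 0.777 with an estimated correlation), with Rpl3 at 0.66 ± 0.11. That call ended without Cre-positive MI 2 (0.0733), Cre-positive MI 3 (0.0716), Cre-positive sham 3 (0.355), Cre-negative sham 1 (0.0539) or Cre-negative sham 3 (0.0515).

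Lists not called in Cre-positive hearts are given in the same way. Hippo components stood at 6 and 3 of 23 (0.09, 0.858), with Vgll3 at 1.97 ± 0.27 and Nf2 at -0.46 ± 0.13. Resting fibroblast markers stood at 7 and 2 of 16 (0.65, 0.173), with Mfap5 at 2.99 ± 0.22 and Gsn at -0.74 ± 0.17. Resident macrophage markers stood at 3 and 0 of 10 (0.72, 0.186), endothelial markers at 0 and 3 of 17 (0.05, 0.627), with a mean of -0.06, lymphatic markers at 1 and 2 of 7 (0.21, 0.859) and markers of smooth muscle and pericytes at 4 and 2 of 14 (0.14, 0.657). Atrial markers stood at 2 and 1 of 6 (0.65, 0.51), nerve markers at 3 and 0 of 10 (0.47, 0.222) and erythrocyte markers at 0 and 0 of 8 (1.02, 0.579). Glycolysis stood at 6 and 8 of 24 (-0.20, 0.318), with a mean of 0.15, with Pgam1 at 0.73 ± 0.12 and Ldhb at -0.97 ± 0.12. Hypoxia genes stood at 4 and 2 of 18 (-0.07, 0.784), the unfolded protein response at 6 and 1 of 22 (0.16, 0.293), immediate early genes at 5 and 0 of 24 (0.37, 0.0795), angiogenic growth factors at 6 and 3 of 23 (0.40, 0.26) and Y-linked genes at 1 and 0 of 4 (6.06, 0.654). Without Cre-positive sham replicate 2, immediate early genes (1.05, 0.00059), the unfolded protein response (0.32, 0.0189) and glycolysis (-0.42, 0.0393) were called, and the atrial median was 2.61.

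By the same test 6179 genes changed in Cre-positive hearts, 3514 up and 2665 down, of which 2113 rose and 205 fell by at least 2-fold. The deposited table of the authors held 5006. Adjusted over the list alone, the calls differed by no more than 3 genes in each list, among them 24 of 24 macrophage markers. Of 42 lists 26 were called with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.0543) and 31 by fry. Across the 13678 genes, which are not independent replicates, the injury responses of the genotypes had a Pearson r of 0.891 ± 0.03 (jackknife SE) and a Spearman rho of 0.888. Of 8185 genes called in either genotype, 3168 rose in both, 2248 fell in both and 2 moved in opposite directions, and the median ratio of the Cre-positive to the Cre-negative log2 fold change was 0.818 ± 0.086 (jackknife SE).

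**Figure D2:**
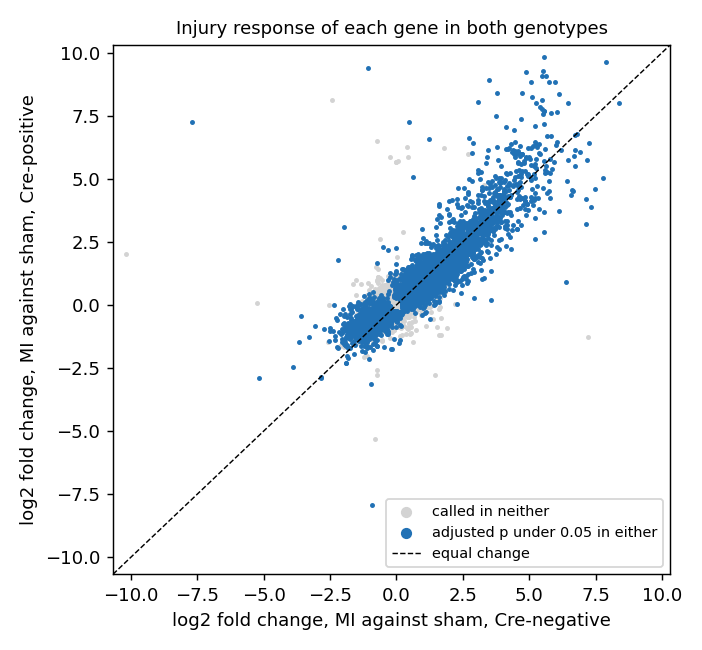
Log2 fold change after MI against sham in Cre-negative (horizontal) and Cre-positive (vertical) hearts, 1 point per tested gene. Genes called in both comparisons lie along a common diagonal, with 3168 rising in both and 2248 falling in both.

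The central comparison asked how hearts with Yap targeted in Postn-expressing cells differ from Cre-negative hearts after infarction. No gene passed the test, whose spread was estimated over all 4 groups, and the genes nearest to it were higher in Cre-positive hearts. Abcc8, a subunit of the ATP-sensitive potassium channel, had a log2 difference of 0.66 ± 0.10 (SE, n = 3 per group), Pcp4l1 of 0.82 ± 0.13, Mettl7a1 of 0.54 ± 0.09, Mreg of 0.72 ± 0.12 and the ubiquitin ligase subunit gene Asb14 of 0.63 ± 0.11, each with an adjusted p of 0.187. Postn was lower at -1.35 ± 0.28 (95% interval -1.95 to -0.74, adjusted p = 0.202), with every Cre-positive MI library below every Cre-negative one. Yap1 differed by 0.02 ± 0.09 (95% interval -0.18 to 0.21).

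Many of the gene groups that rise with infarction lay lower in Cre-positive MI hearts, relative to all other genes, although none of their members passed the test on its own. The 37 cell cycle genes had a median log2 difference of -0.54 (adjusted p = 1.32e-11, 0.239 with an estimated correlation), and 21 of them were lower adjusted over the list alone, such as Ccnb2 (-0.82 ± 0.17) and Mcm6 (-0.54 ± 0.12). Myofibroblast markers had a median of -0.43 (adjusted p = 9.1e-06, 0.257 with an estimated correlation) with 5 lower adjusted over the list alone, among them Wisp1 (-0.54 ± 0.10), and the MRTF and SRF targets -0.38 (adjusted p = 4.9e-06, 0.239 with an estimated correlation) with 8, among them Flna (-0.45 ± 0.12). Collagens had a median of -0.40 (adjusted p = 1.98e-05, 0.451 with an estimated correlation), other matrix genes -0.40 (2.9e-07, 0.239 with an estimated correlation) and proteases -0.39 (0.000302, 0.239 with an estimated correlation), each with 3 lower adjusted over the list alone, including Col12a1 (-0.65 ± 0.15), Fbln2 (-0.47 ± 0.11) and Adam12 (-0.84 ± 0.17). Macrophage markers had a median of -0.41 (adjusted p = 3.17e-05, 0.451 with an estimated correlation) with 2 lower adjusted over the list alone, Chil3 (-1.33 ± 0.31) and Cd68 (-0.68 ± 0.19), and cytokines -0.47 (adjusted p = 0.000581, 0.451 with an estimated correlation) with 1, Spp1 (-0.84 ± 0.19). TGF-beta signalling genes had a median of -0.19 (adjusted p = 0.00381, 0.239 with an estimated correlation) with 1 lower adjusted over the list alone, Tgfbi (-0.65 ± 0.12). Neutrophil markers had a median of -0.80 (adjusted p = 0.0273, 0.452 with an estimated correlation), but only -0.50 (0.289) without Cre-positive MI replicate 1 and -0.31 (0.228) without Cre-negative MI replicate 2, where the call ended.

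Other groups that rose in either genotype were not called between the genotypes after MI. Interferon-stimulated genes had a median of 0.01 (adjusted p = 0.992), complement genes 0.09 (0.931) and adipocyte markers 0.99 (0.322), with 10 of 10 above 0. With a term for Y-linked reads, interferon-stimulated genes were called lower (-0.27, 0.00103) and adipocyte markers higher (1.79, 0.000781). The dendritic list had -0.31 (0.355), and -0.30 (0.0226) without Cre-positive sham replicate 2.

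Gene groups that fall with infarction lay higher in Cre-positive MI hearts. Oxidative phosphorylation genes had a median log2 difference of 0.29 (adjusted p = 1.85e-24, 0.239 with an estimated correlation) with 15 of 51 higher adjusted over the list alone, such as Ndufb9 (0.37 ± 0.09). Fatty acid oxidation genes had 0.43 (adjusted p = 2.44e-12, 0.263 with an estimated correlation) with 1, Etfb (0.42 ± 0.10), and tricarboxylic acid cycle genes 0.33 (adjusted p = 2.2e-12, 0.239 with an estimated correlation) with 4, among them Suclg2 (0.41 ± 0.10). Cardiomyocyte genes had 0.36 (adjusted p = 3.88e-08, 0.263 with an estimated correlation) with 3, among them Pln (0.49 ± 0.15), and ion channel genes 0.24 (adjusted p = 4.59e-06, 0.239 with an estimated correlation) with 6, among them Kcnj11 (0.49 ± 0.12). The circadian list had 0.32 (adjusted p = 0.0103, 0.239 with an estimated correlation) with 2, Hlf (0.67 ± 0.16) and Tef (0.49 ± 0.15), and lost its call without Cre-positive MI replicate 1 (0.0801). The 23 YAP and TEAD targets had a median of -0.12 and were not called (adjusted p = 0.191), with Myof (-0.57 ± 0.16) and Cyr61 (-0.54 ± 0.15) lower adjusted over the list alone. The Hippo components had a median of -0.07 (adjusted p = 0.186) with 0 genes called either way. Y-linked genes had a median of -1.71 (adjusted p = 0.00179, 0.356 with an estimated correlation), a measure of the uneven sexes. Markers of the atria (median 0.73, adjusted p = 0.0234, 0.452 with an estimated correlation) and of the epicardium (0.36, 0.0246, 0.452 with an estimated correlation), listed as checks on dissection, were higher. The epicardial list does not report on dissection alone, since it was also called higher with infarction in Cre-positive hearts (median 1.16). The atrial call ended without Cre-positive MI replicate 1 (0.0733) or Cre-negative MI replicate 1 (0.116) or 2 (0.0617), and the epicardial call without Cre-positive MI replicate 1 (0.352), Cre-negative MI replicate 2 (0.115) or Cre-positive sham replicate 1 (0.0582) or 2 (0.0776).

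**Figure D3:**
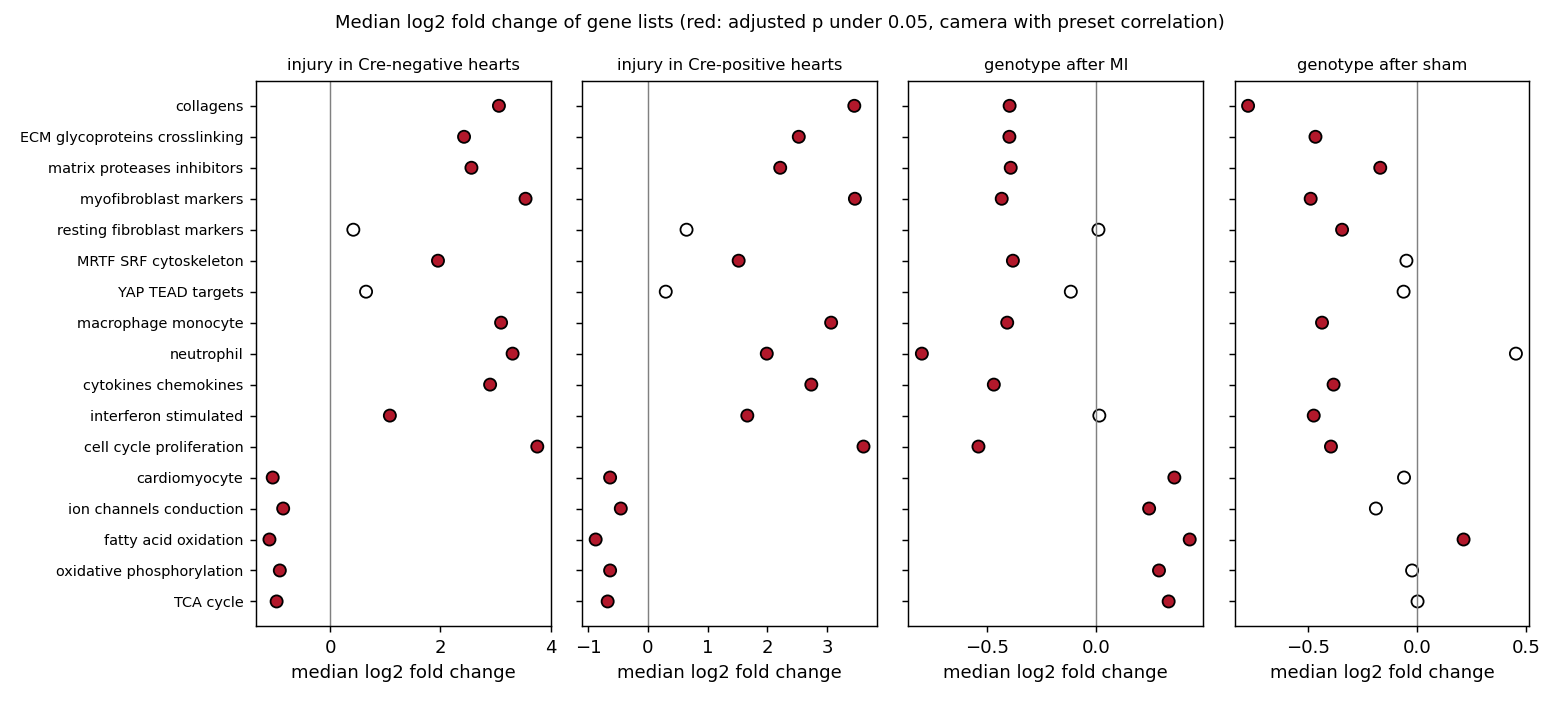
Median log2 fold change (horizontal) of selected gene lists (vertical) in the 4 pairwise comparisons, red where the list was called with the preset correlation. Between the genotypes after MI, collagens lie at -0.40 and cell cycle genes at -0.54, and oxidative phosphorylation genes at 0.29.

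The edgeR test called 0 genes between the genotypes after MI, with 1728 at an unadjusted p under 0.05 where 684 are expected by chance, while the DESeq2 Wald test called 177 (87 higher, 90 lower), limma-trend on log2(FPKM + 1) called 42 and on log2(FPKM + 0.1) called 0. In 3717 genes (27.2%) the 3 libraries of each genotype did not overlap, where chance gives 10%, and the deposited table of the authors held 763 genes with an adjusted p under 0.05, 18 of them changed by at least 2-fold. Without Cre-positive sham replicate 2, edgeR called 3 genes, among them Pcp4l1 (0.83) and Postn (-1.33), each with an adjusted p of 0.0136. That library is not part of this comparison and enters it only through the fit shared by all groups. An edgeR fit to only the 2 MI groups called 1 gene, Postn (-1.34, adjusted p = 0.00261). The count of 0 therefore does not show that no gene differs. Of 42 lists 21 were called, 8 higher and 13 lower, 0 of them with an estimated correlation or by fry.

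After sham surgery 7 genes were lower in Cre-positive hearts, 3 of them (Cthrc1, Postn and Tnc) among the myofibroblast markers. Cthrc1 was lower by -4.56 ± 0.51 on the log2 scale (SE, n = 3 per group, adjusted p = 0.00494), Sprr1a by -3.86 ± 0.50 (0.0119), Postn by -3.36 ± 0.32 (0.00227), Tnc by -3.22 ± 0.32 (0.00227) and Spp1 by -2.56 ± 0.35 (0.0176). Aspn, which encodes the small proteoglycan asporin, was lower by -1.14 ± 0.15 (0.0119) and the butyrylcholinesterase gene Bche by -0.84 ± 0.10 (0.00733). In Cre-negative sham hearts Tnc had 9.92 ± 2.43 CPM and Cthrc1 4.50 ± 1.58 CPM, against 374 ± 52.3 and 132 ± 14.4 CPM after MI (SD, n = 3), and in Cre-positive sham hearts they had 1.04 ± 0.541 and 0.191 ± 0.208 CPM. All of these genes except Bche rose after MI in both genotypes. Cthrc1 and Sprr1a held 6 and 13 reads over the 3 Cre-positive sham libraries, so the sizes of their differences are uncertain. Bche had 65.4 ± 3.24 CPM in Cre-negative sham, 36.5 ± 3.24 in Cre-positive sham, 45.4 ± 4.58 in Cre-negative MI and 42.2 ± 1 in Cre-positive MI libraries.

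**Figure D4:**
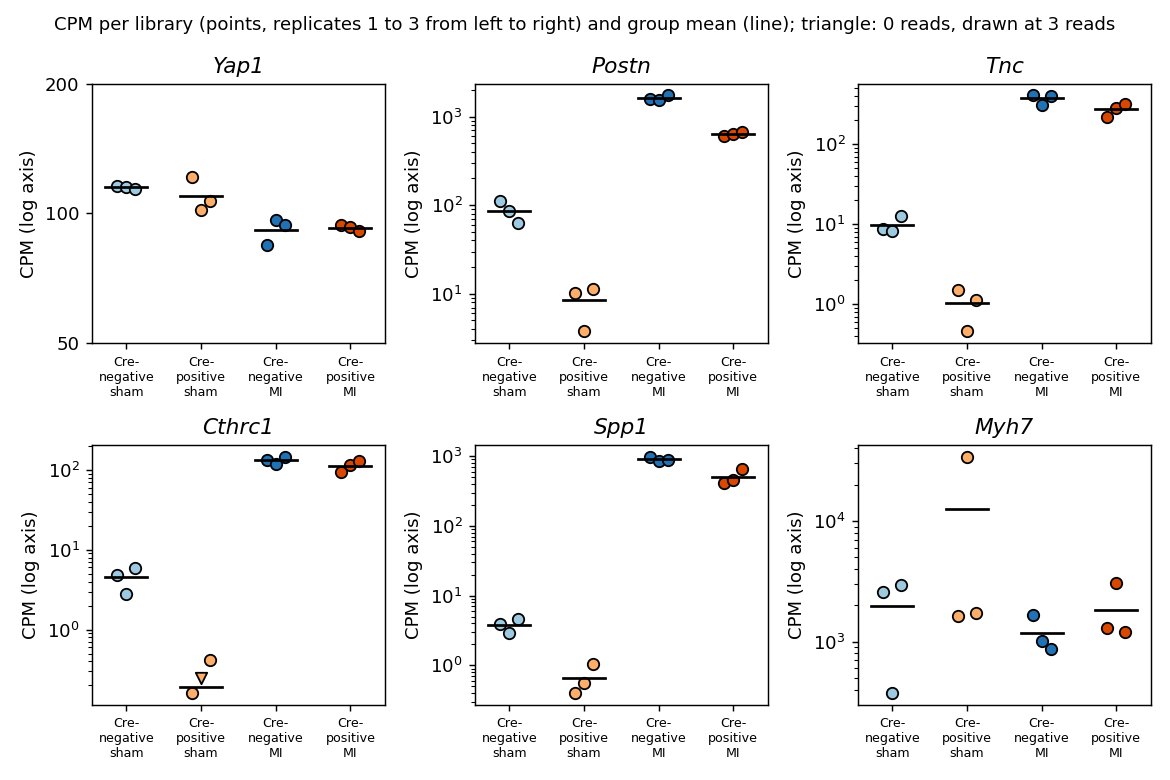
CPM (vertical, log axis) of Yap1, Postn, Tnc, Cthrc1, Spp1 and Myh7 in each of the 12 libraries by group, with the group mean as a line and a library with 0 reads as a triangle at 3 reads. Postn, Tnc, Cthrc1 and Spp1 are lower in every Cre-positive than in every Cre-negative sham library, and Myh7 stands at 34060 CPM in Cre-positive sham replicate 2.

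Matrix lists were lower as groups in Cre-positive sham hearts. Collagens had a median log2 difference of -0.77 (adjusted p = 2.24e-13, 0.312 with an estimated correlation) with 8 of 19 lower adjusted over the list alone, such as Col12a1 (-1.38 ± 0.25) and Col5a2 (-1.08 ± 0.20), and the median was -0.36 without Cre-positive sham replicate 2. Other matrix genes had -0.46 (adjusted p = 3.16e-12, 0.215 with an estimated correlation), with Postn and Tnc lower and 9 of 36 lower adjusted over the list alone, such as Ltbp2 (-1.76 ± 0.34), and -0.31 without that library. Myofibroblast markers had -0.49 (adjusted p = 5.56e-11, 0.215 with an estimated correlation), with 3 lower and 5 adjusted over the list alone, and -0.22 without it. The chondrogenic and osteogenic list had -0.43 (adjusted p = 0.00115, 0.199 with an estimated correlation), with Spp1 lower, and 3 adjusted over the list alone, such as Cilp (-1.49 ± 0.46). Proteases and inhibitors had -0.17 (adjusted p = 0.00115, 0.312 with an estimated correlation) with 4 lower adjusted over the list alone, such as Timp1 (-2.15 ± 0.45), and lost the call without Cre-positive sham replicate 3 (0.0579), while the median was -0.29 without replicate 2. Cell cycle genes had -0.39 (adjusted p = 4.8e-06, 0.377 with an estimated correlation), with 0 of 37 lower by either adjustment, and -0.59 without Cre-positive sham replicate 2.

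Several other groups depended on Cre-positive sham replicate 2, the library with raised Myh7. Macrophage markers had a median of -0.43 (adjusted p = 1.24e-06, 0.442 with an estimated correlation) with Ccr2 (-2.04 ± 0.38) lower adjusted over the list alone, cytokines -0.38 (0.000344, 0.452 with an estimated correlation), interferon-stimulated genes -0.47 (7.65e-08, 0.512 with an estimated correlation) and the dendritic list -0.46 (0.00287, 0.442 with an estimated correlation). Without that library their medians were -0.12, -0.06, -0.11 and 0.06, and they were not called (adjusted p = 0.109, 0.398, 0.0851 and 0.554). Fatty acid oxidation genes had 0.22 (adjusted p = 0.00287, 0.719 with an estimated correlation) and turned to -0.04 without it (0.485). They also lost their call without Cre-negative sham replicate 3 (0.17, 0.0909). The unfolded protein response list had 0.20 (adjusted p = 0.00019, 0.452 with an estimated correlation) and lost its call without Cre-positive sham replicate 2 (0.732). Resting fibroblast markers had -0.34 (adjusted p = 0.00756, 0.442 with an estimated correlation) and lost their call without Cre-positive sham replicate 2 (0.111) or 3 (0.0854) or Cre-negative sham replicate 1 (0.0531). Ribosomal protein genes had 0.16 (adjusted p = 5.56e-11, 0.442 with an estimated correlation) and Y-linked genes -7.46 (0.00251, 0.442 with an estimated correlation). Both stayed called without Cre-positive sham replicate 2 (1.67e-05 and 0.00918). YAP and TEAD targets had a median of -0.06 and were not called (adjusted p = 0.189), but were without Cre-positive sham replicate 2 (-0.09, 0.0168). Hippo components (0.05, 0.784) and cardiomyocyte genes (-0.06, 0.553) were not called. Further lists were called only without that library, namely oxidative phosphorylation (0.11, 0.00147), glycolysis (0.19, 0.000858), neutrophil (0.58, 0.0246) and atrial markers (-1.52, 0.0165).

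By edgeR the count after sham surgery was 7 genes, all lower, with 1125 at an unadjusted p under 0.05 and no overlap between the genotypes in 1456 genes (10.6%, where chance gives 10%). The deposited table of the authors held 12, all lower. When only the 2 sham groups were fitted, 0 genes passed in edgeR (DESeq2 called 39 over all 12 libraries), with a log2 difference of -3.37 for Postn. Libraries of the same Y-linked status also gave 0, but set 3 Cre-positive against 1 Cre-negative sham library, too few to decide. Single libraries ended the calls of Sprr1a (Cre-positive sham 1, 2 or 3 or Cre-negative sham 1, adjusted p = 0.0598, 0.0854, 0.0585 and 0.0571), Spp1 (Cre-positive sham 1 or 2 or Cre-negative sham 1 or 3, 0.0974, 0.112, 0.0907 and 0.105), Aspn (Cre-negative sham 1, 0.0571) and Bche (Cre-negative sham 1 or 3, 0.0571 and 0.0617), and without Cre-negative sham replicate 1 the count was 3.

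The last comparison tested whether infarction changed genes by different amounts in the 2 genotypes. The rises of Cthrc1 and Tnc were larger in Cre-positive hearts by 4.34 ± 0.58 and 2.78 ± 0.39 on the log2 scale (SE, n = 3 per group), short of the threshold at an adjusted p of 0.0777 each. They started from lower sham levels (0.191 and 1.04 CPM, against 4.50 and 9.92 CPM in Cre-negative hearts). After MI the means were not higher in Cre-positive hearts (113 and 275 CPM, against 132 and 374 CPM). Cthrc1 held 6 reads over the 3 Cre-positive sham libraries, near the floor, so the size of its difference is uncertain. Sprr1a had a difference of 3.47 ± 0.58, the tubulin gene Tubb6 of -0.95 ± 0.16 (adjusted p = 0.264 each) and the glycolytic gene Pgam1 of -0.89 ± 0.16 (0.361). Postn, named in advance, had a difference of 2.01 ± 0.41 (adjusted p = 0.496 over all genes and adjusted p = 0.000682 over Postn and Yap1 alone), in which its lower sham level takes part, and Yap1 one of 0.08 ± 0.12 (adjusted p = 0.887).

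Among gene groups, those of muscle and energy metabolism had a higher median difference than other genes, although none of their members passed. Oxidative phosphorylation genes had a median difference of 0.30 (adjusted p = 3.09e-16, 0.495 with an estimated correlation), tricarboxylic acid cycle genes 0.30 (3.97e-08, 0.495 with an estimated correlation), cardiomyocyte genes 0.45 (5.06e-06, 0.495 with an estimated correlation, median 0.24 without Cre-positive sham replicate 2) and ion channel genes 0.37 (9.53e-06, 0.495 with an estimated correlation). Neutrophil markers had a median difference of -1.10 (adjusted p = 0.00233, 0.495 with an estimated correlation) and MRTF and SRF targets of -0.27 (0.000192, 0.495 with an estimated correlation). Adjusted over the list alone, 0 members of these 6 lists passed. The YAP and TEAD targets had a median difference of -0.08 (adjusted p = 0.985).

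No gene passed the interaction test in edgeR, with 1116 at an unadjusted p under 0.05, while DESeq2 called 34 genes (21 higher, 13 lower) and limma-trend on log2(FPKM + 1) called 0. With no filter on low counts Cthrc1 and Tnc passed in edgeR (adjusted p = 0.0336 each), and without Cre-negative sham replicate 2 Cthrc1 alone did (0.0266). Of 42 lists 13 were called, 9 higher and 4 lower, and 0 with an estimated correlation or by fry.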

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

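The explanations weighed here and the tests of them were chosen only after the results had been seen. After MI, genes called as changed in both genotypes lay nearer to sham levels in Cre-positive hearts, with a median log2 difference in the direction of injury of -0.239 (SE 0.066) over 5416 genes. This is a difference of levels after MI, whereas for the change from sham the median ratio of Cre-positive to Cre-negative hearts was 0.818 (SE 0.086) over 8185 genes, and the median of collagens was 3.46 against 3.06, or 3.08 against 3.04 without Cre-positive sham replicate 2. A term for Y-linked reads left it at -0.262 (SE 0.088). That term rests on Cre-positive MI (1 of 3 libraries with such reads) and Cre-negative sham (2 of 3), so the uneven sexes are not settled. In 20 simulated data sets without a genotype difference after MI the lowest value was -0.013, against a bias from choosing genes in the shared libraries. The fitted differences between the sham groups were kept there. Genes were drawn independently in these data sets, so library shifts common to many genes were not covered. Of 397 genes that rose at least 8-fold in both genotypes, 91.2% were lower in Cre-positive MI hearts (median -0.52), a share that restates the pattern. After sham surgery 81.9% of them were lower in Cre-positive hearts (median -0.66). The sham libraries took part in choosing these genes, so that share decides nothing. Less injured tissue in the Cre-positive MI samples, the uneven sexes, Yap loss and the recombinase itself cannot be told apart.

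After sham surgery, 7 genes were called lower in Cre-positive hearts, 3 of them in the list of myofibroblast markers, with a median log2 difference of -3.221 (SE 0.538). The median was -3.302 (SE 0.567) with the term for Y-linked reads, but 0 of 3 Cre-positive sham libraries had such reads, so the uneven sexes are not settled. Against the 1 Cre-negative sham library without such reads Postn still differed by -3.357, which a single library cannot decide. Without Cre-positive sham replicate 2, 5 of the 7 passed the same test, against that library as their cause. Spp1 (-2.45) and Sprr1a (-3.38) kept most of their difference but were 2 genes no longer called. For Postn the upper 95% limit was -2.667, so the loss of the transcript of 1 allele, a log2 change of -1, cannot be the whole fall, whereas after MI the interval of -1.95 to -0.74 includes it. Of the same 397 injury genes, 77.6% were lower in Cre-positive sham hearts without replicate 2, which restates the observation, and the macrophage (-0.12) and cytokine (-0.06) lists were not called without it. The uneven sexes, a wound response in the Cre-negative sham hearts, insertion of the recombinase and loss of Yap in cells that express Postn all stay open.

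Cre-positive sham replicate 2 stood apart from the other sham libraries, with a chi-square per gene of 130 and 96.4 against the other libraries of its group, where all other pairs within groups had 7.22 to 21.2. In it 3 of the 397 injury genes reached the range of the MI libraries, but these genes were chosen with this library counted as sham, so that number decides nothing. On the first principal component, which uses no group labels, it lay at -80.8, against 43.6 to 79.2 in the MI libraries. That position counts against an exchanged MI sample. Reads moved between the paralogs Myh6 and Myh7 are not the whole cause, since 38 other genes lay more than 4-fold outside the other sham libraries. The 10 most abundant genes took 11.8% of its counts, against 13.8 to 15.3% in the other sham libraries, so no few genes crowd out the rest. A different state or handling of that heart could remain as the cause, and the labels record neither.

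The number of genes called was compared with the same count after exchanging libraries between groups. Each pairwise comparison has 10 distinct splits of its 6 libraries, too few for a share under 0.05. The real grouping was 1 of 10 in each, with 7424 genes against at most 1 for injury in Cre-negative hearts, 6179 against at most 0 in Cre-positive hearts, 1728 at an unadjusted p under 0.05 against at most 748 for genotype after MI, and 7 against at most 3 after sham surgery. In the injury comparisons every other split mixed MI with sham libraries, which widens the spread within groups. Few calls in those splits were thus given in advance and lend the real counts no weight. At an unadjusted p under 0.05 they held 69 to 206 genes in Cre-negative hearts, where 684 are expected by chance. By the unadjusted count after sham surgery, 4 other splits exceeded the 1125 genes of the real grouping, the highest with 1653. For the difference of the injury response, 10 of 100 splits had at least the 1116 genes of the real grouping at an unadjusted p under 0.05, with 1779 as the highest other count. That count could therefore have arisen by chance, and the splits did not test single genes such as Postn.

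The test of the difference itself called no gene over all genes, and the lists given here were called only with the preset correlation, 0 of them with an estimated correlation (smallest adjusted p = 0.495) or by fry. Postn had a difference of 2.012 on the log2 scale, adjusted over Postn and Yap1. Among lists, the median log2 difference was 0.435 for collagens, 0.07 for myofibroblast markers, 0.21 for resting fibroblast markers and 0.459 for interferon-stimulated genes, and without Cre-positive sham replicate 2 these were 0.003, -0.205, 0.11 and 0.134 and no longer called (adjusted p = 0.905, 0.316, 0.236 and 0.313). The myofibroblast call also ended without Cre-positive MI replicate 3 (0.162), Cre-negative MI replicate 1 (0.0574) or 2 (0.086), Cre-positive sham replicate 3 (0.0504) or Cre-negative sham replicate 1 (0.0786) or 2 (0.163). The resting fibroblast call ended without Cre-positive MI replicate 1 (0.0778), Cre-negative MI replicate 3 (0.0737), Cre-positive sham replicate 3 (0.105) or Cre-negative sham replicate 1 (0.0792) or 2 (0.0577), and the interferon call without Cre-negative sham replicate 2 (0.0577). The median difference was -0.265 for MRTF and SRF targets and -1.096 for neutrophil markers. Genes of the heart muscle had 0.448, and 0.237 without Cre-positive sham replicate 2, ion channels 0.368, oxidative phosphorylation 0.295 and the tricarboxylic acid cycle 0.299. Fatty acid oxidation had 0.187 and lost its call without Cre-positive sham replicate 1 (adjusted p = 0.262) or 3 (0.106) or Cre-negative sham replicate 1 (0.0965), whereas it had 0.481 (4.98e-12) without Cre-positive sham replicate 2. The unfolded protein response had -0.427, and -0.24 (0.043) without that library, where a term for Y-linked reads ended the call (0.0511). Macrophage (-0.35, 0.00722) and atrial (2.07, 0.000833) markers were called only without that library. Ribosomal proteins had -0.222.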

How the results depend on the processing

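Results were refitted with the settings chosen before the data were examined, and with the Y-linked settings chosen after seeing the data. Against a fold of 1.5 (glmTreat), 3202 genes were called in Cre-negative and 2186 in Cre-positive hearts. In Cre-positive hearts the count was 4630 with only the 2 groups compared and 4886 with the same Y-linked status, against 6179 in the full fit. With single libraries left out the counts were 6345 to 8360 and 5060 to 6603. On the FPKM scale, limma-trend placed 75.5% and 81.9% of the called genes higher after MI, against 55.1% and 56.9% in the edgeR fit, and the median of all genes was 0.2 and 0.185 against 0.024 and 0.015 on the log2 scale. The FPKM fits did not apply the TMM factors. These were 1.085 to 1.137 in Cre-negative MI against 0.907 to 0.977 in Cre-negative sham libraries. In Cre-positive hearts they were 1.04 to 1.076 after MI against 0.893 to 0.914 after sham surgery. Leaving them out raises values after MI relative to sham, the direction of this shift. The Pearson r between the injury responses was 0.932 with limma-trend on log2(FPKM + 1), 0.682 with no filter on low counts and 0.853 to 0.882 with single libraries left out. The fits with a library left out kept 13785 to 13856 genes, against 13678 in the full fit. That range and the jackknife SE thus mix a change of genes with the effect of a library.

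For genotype after MI, where edgeR called 0 genes, the DESeq2 Wald test called 177 and limma-trend on log2(FPKM + 1) called 42 (3 higher, 39 lower). The limma-trend fit, which left out the TMM factors, placed the median of all genes at -0.057, against -0.007 in edgeR. A fit to only the 2 groups compared called 1, and leaving out single libraries gave 0 to 3, the most without Cre-positive sham replicate 2. For genotype after sham surgery, where edgeR called 7, DESeq2 called 39 (11 higher, 28 lower), glmTreat 4, and the Y-linked term without Cre-positive sham replicate 2 also 4. Only the 2 groups compared gave 0 and libraries of the same Y-linked status gave 0, with 1 Cre-negative sham library left to compare. Leaving out single libraries gave 3 to 8, the fewest without Cre-negative sham replicate 1. For the difference of the injury response, no filter on low counts gave 2, DESeq2 gave 34 and single libraries left out gave 0 to 1.

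Yap1 after MI in Cre-negative hearts had a log2 fold change of -0.08 (adjusted p = 0.449) and -0.083 (0.448) with limma-trend on FPKM with offsets of 1 and 0.1, and -0.327 (1) with glmTreat. In Cre-positive hearts its call ended with no filter at -0.25 (0.0588), the 5 CPM filter at -0.214 (0.055), limma-trend at -0.014 with either offset (0.908 and 0.91), the replicate number as a block at -0.246 (0.0551), only the 2 groups at -0.236 (0.137), glmTreat at -0.247 (1), the Y-linked term at -0.252 (0.062) and the same Y-linked status at -0.257 (0.0993). With single libraries left out it ranged from -0.339 to -0.172. The limma-trend fits left out the TMM factors, which raises values after MI relative to sham, so they do not test this fall separately. The difference of Yap1 between genotypes after MI turned to -0.049 and -0.051 with limma-trend and ranged from -0.04 to 0.053 with single libraries left out. After sham surgery it ranged from -0.151 to 0.017, and was 0.036 with the Y-linked term and without Cre-positive sham replicate 2.

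Postn between genotypes after MI was called by DESeq2 at -1.346 (adjusted p = 0.00113), limma-trend at -1.412 (0.047) and the fit to only the 2 groups at -1.342 (0.00261), and ranged from -1.391 to -1.295 with single libraries left out. After sham surgery it lost its call with only the 2 groups at -3.371 (0.201) and with the same Y-linked status at -3.357 (0.124). For the difference of the injury response, DESeq2 called it at 1.997 (0.00119). Against a fold of 1.5, Spp1, Aspn and Bche were not called after sham surgery (0.0728, 0.598 and 1), and limma-trend did not call Tnc (0.0523). The Y-linked term ended the calls of Spp1 at -2.634 (0.102) and Bche at -0.814 (0.102), with differences close to the -2.56 and -0.84 of the full fit.

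With an estimated correlation 0 lists were called in each of the 5 contrasts. By fry 0 were called for genotype after MI, 3 after sham surgery and 0 for the difference of the injury response. The Y-linked list turned its direction of test with the Y-linked term, at -0.122 after MI and 0.641 after sham surgery, and at -0.108 and 1.202 without Cre-positive sham replicate 2 as well. Fatty acid oxidation after sham surgery ranged from -0.043 to 0.372 with single libraries left out. Of the named genes other than Yap1, 0 turned their sign under any setting.

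Replicate numbers gave a mixed picture of pairing between the libraries. Of 18 pairs with the same number in different groups, 4 had a correlation of residuals above 0.1. The mean was 0.037 against -0.018 for pairs with different numbers. For 8 of 12 libraries, however, the mean correlation with libraries of other groups was highest for their own number. With the number as a block, 7370, 6150, 0, 7 and 0 genes were called in the 5 contrasts, and the T and NK cell list in Cre-positive hearts lost its call (0.0582).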

Other observations

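In Cre-positive sham replicate 2 the mean log2 CPM of the cardiomyocyte list was 11.1, against 11.4 to 11.6 in the other sham libraries, and the single genes given here were picked after their values were seen. Its sum of Myh6 and Myh7 was 48400 CPM, within the 40210 to 54870 CPM of the other sham libraries, so the myosin genes changed their shares and not their sum. The fuel switch gene Pdk4 stood at 2243 CPM against 60.5 to 534 CPM in the other sham libraries. The glucocorticoid-responsive gene Fkbp5 had 184 CPM, the stress genes Atf3 and Nr4a3 115 and 160 CPM and the cell cycle inhibitor gene Cdkn1a 206 CPM. Lower values were those of Col3a1 at 21.7 CPM against 150 to 555, Col1a1 at 28.2 against 114 to 446 and Cd74 at 13.7 against 97.3 to 130 CPM.

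The unfolded protein response and ribosomal protein lists, which rose with infarction in Cre-negative hearts, lay slightly lower in Cre-positive MI hearts. The unfolded protein response had a median log2 difference of -0.20 (adjusted p = 0.0165, 0.652 with an estimated correlation), with Edem1 at -0.47 ± 0.13 and Herpud1 at 0.72 ± 0.17, and lost its call without Cre-positive MI replicate 1 (0.0733). Ribosomal proteins had -0.07 (adjusted p = 0.00871, 0.825 with an estimated correlation) and lost their call without Cre-positive MI replicate 1 (0.227) or Cre-negative MI replicate 1 (0.606). The lymphatic marker gene Pdpn lay at -0.60 ± 0.13.

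The paralogs Eif3j1 and Eif3j2 divided their reads unevenly between libraries. Eif3j1 held 0, 1.01 and 1.04% of their joint reads in Cre-positive sham replicate 1 and Cre-negative sham replicates 1 and 2, and 95.2, 98.8 and 99.4% in Cre-negative MI replicate 2 and Cre-positive sham replicates 3 and 2. The other 6 libraries had 38.9 to 55.2%. Values of either gene alone are therefore best read as their sum.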
